A study of Homo sapiens with 128 samples.

How the data were processed

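RNA sequencing was compared between knockdowns of 20 genes put forward as regulators of transcription in breast cancer metastasis, in 4 human breast cancer cell lines. Per the labels, total RNA was purified with an RNeasy kit and libraries were made by a standard Illumina protocol. Whether the libraries kept strand information is not given in the sources used here, so a gene and an antisense gene that overlaps it cannot be told apart.

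The deposited table holds raw counts per gene, with 20676 lines and 1 column for each of 128 libraries. Per the submitters' processing notes, the authors used the hg19 genome build, STAR 2.4.0d, featureCounts from Subread and DESeq, and the counts analysed here are whole numbers that were not normalised. Genes are given as Entrez identifiers. The 15 identifiers that stood on 2 lines were summed, which left 20661 genes, and 20515 of them were matched to a symbol through a table of gene names. The other 146 were tested without a name. Coordinates are on hg19, from a GENCODE annotation lifted to that build.

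Libraries were assigned to a cell line and a target from their labels, which gave 64 groups of 2 libraries. Each line has 16 groups, made of 14 knockdowns, a mock control and a scramble control. Of 20 targets, 8 were knocked down in all 4 lines and 12 in 2 lines. The labels do not say that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Totals ranged from 38599030 to 62033626 counts per library. A count of 0 in 1 library allows a level of up to 0.0484 to 0.0777 CPM (counts scaled to a total of 1e6), taking 3 counts as the floor. Folds against a group with no reads were bounded with 3 counts over the group's 2 libraries. Intervals and floors cover counting error only. Of the counts from 1 to 20, 77.9% were even, so that low counts move in steps larger than 1. If each read pair was counted as 2 reads, the floors would be 2 times as high and each bound on a fold smaller by up to 1 log2. Replicate libraries differed by more than sampling noise (chi-square per degree of freedom 2.48 to 66.8, median 14.3), and no group was treated as 1 library deposited in duplicate.

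Counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM scaling and Benjamini-Hochberg adjustment, and genes with an adjusted p under 0.05 were called. In 1 fit over all 128 libraries, the default filter (minimum count 10, minimum total 15) left 15390 genes. Each knockdown was compared with scramble inside its own line and averaged over its lines. TRIM25 was also tested within each line, in fits of that line's 32 libraries, and as a difference between the lines T47D and MCF7 and the lines BT549 and MDAMB231. Scramble was compared with mock. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 20 lists and 20 targets, and again with the correlation estimated from the data. CPM are given as mean ± SD over the libraries of a group, and log2 fold changes with their standard error (SE).

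The following were fixed before the data were examined: the groups, these tests, the alternatives and 22 gene lists taken from textbook knowledge. The lists cover interferon-stimulated genes, NF-kB targets, DNA replication, mitosis, replication-dependent histones, p53 targets, ATF4 targets, ER chaperones, cholesterol synthesis, cytosolic ribosomal proteins, nucleolar ribosome assembly, nuclear oxidative phosphorylation, hypoxia and glycolysis, MAPK and immediate early genes, YAP and TGF-beta targets, oestrogen-responsive genes, epithelial genes, mesenchymal and matrix genes, breast cancer metastasis genes, and stromal and immune cell markers. Metallothionein genes, with 5 members in the table, and mitochondrially encoded genes, with 0, were listed but not tested. The rule for named genes took, among called genes with an average of at least 2 log2 CPM and the same sign in every line, the 10 largest rises and 10 largest falls for TRIM25 and 4 of each for every other target. It took 3 of each for TRIM25 within a line, 5 of each for the difference between the pairs of lines and for scramble against mock, up to 4 members of a called list, and every targeted gene.

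The other settings tried were RLE size factors, no low-count filter, the Wald test of DESeq2 1.42.0, mock libraries or both controls as the control, the mean of the other knockdowns of the same line as the reference, leaving out each line, and leaving out each replicate. Mainly because scramble libraries lay far from all others, 4 additions were chosen after seeing the data. Results against the mean of the other knockdowns are given beside those against scramble. The rule for named genes was repeated on that reference with at least 4 CPM in the knockdown or in the other knockdowns of every line tested, since the first rule named genes near 0 in the lines concerned. A term for the side of the first principal component on which a T47D library lay was added to the fit, and so was a term per line for the order of the 2 libraries of a group. All comparisons against scramble share the same scramble libraries, and those against the other knockdowns share libraries too, so counts of calls are not compared by their overlap.

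The procedure was tested on simulated data with 200 changed genes. For TRIM25 against scramble over 4 lines (15116 genes), 89.5% of genes changed by 0.5 log2 and 92.6% of those changed by 1 were recovered, and 4.2% of calls were false. For CTBP1 against scramble over 2 lines, 83.7% and 94.4% were recovered with 2.7% false calls. For TRIM25 against the mean of the other knockdowns the shares were 96.2% and 92.6% with 5.5% false calls, and for TRIM25 within T47D alone (13242 genes) 71.2% and 93.5% with 3% false calls. The simulated libraries were independent and held neither a shift of scramble nor the T47D sides, so these shares may not hold for the real data. Between TMM and RLE scaling the share of higher calls moved by at most 5.6 percentage points and the median log2 change of all genes by at most 0.029.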

Results

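RNA was sequenced from 4 breast cancer cell lines, BT549, MDAMB231, T47D and MCF7, after knockdown of genes put forward as regulators of transcription in breast cancer metastasis. The data comprise 128 libraries in 64 groups of 2, with 14 knockdowns, a mock and a scramble control in each line. TRIM25, FOXD4L6, ZNF589, CNBP, HOXA11, PRRX1, IRX6 and TSHZ3 were knocked down in all 4 lines. CTBP1, ZNF581, YBX1, RPL7, FOXQ1 and BNC2 were knocked down in BT549 and MDAMB231 only, and PAX5, ZNF253, ZNF142, CBFA2T2, ZMAT4 and NKX6 in T47D and MCF7 only. Total counts per library were 38599030 to 58555944 in BT549, 43409702 to 54661318 in MDAMB231, 41965185 to 58940542 in T47D and 43746406 to 62033626 in MCF7.

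The lines differed in their markers as measured in the 4 control libraries of each. ESR1, the oestrogen receptor, stood at 176 ± 87.0 CPM (SD, n = 4) in T47D and 185 ± 65.2 CPM in MCF7, against 0.0886 CPM in BT549 and 0.0209 CPM in MDAMB231. GATA3, a luminal transcription factor, stood at 833 ± 75.4 CPM in T47D and 1313 ± 104 CPM in MCF7, and at 20.2 and 18.7 CPM in BT549 and MDAMB231. VIM, the intermediate filament of mesenchymal cells, stood at 3056 ± 444 CPM in BT549 and 2666 ± 293 CPM in MDAMB231 but at 2.03 and 1.46 CPM in T47D and MCF7. ERBB2 stood at 100.7, 102.4, 198 and 185 CPM in BT549, MDAMB231, T47D and MCF7. The median of the epithelial genes was 0.524 CPM in BT549, 5.11 in MDAMB231, 211 in T47D and 229 in MCF7, and that of the mesenchymal and matrix genes was 171, 33.4, 0.50 and 1.42 CPM in the same order. For the oestrogen-responsive genes it was 8.55, 1.88, 111 and 62.8 CPM.

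The targeted genes were examined first. TRIM25, a ubiquitin ligase also known for its part in RNA sensing (Entrez 7706, chromosome 17, 54913748 to 54991441 on hg19, minus strand), fell in every line in which it was targeted. Its level was 4.96 ± 1.55 CPM (SD, n = 2) after knockdown in BT549 against 333 ± 6.71 CPM in scramble and 137 ± 3.61 CPM in mock. In MDAMB231 it was 30.8 ± 8.0 CPM against 312 ± 14.2 and 245 ± 0.202 CPM, in T47D 18.0 ± 1.5 CPM against 518 ± 2.78 and 194 ± 24.6 CPM, and in MCF7 112 ± 1.05 CPM against 558 ± 29.4 and 303 ± 7.08 CPM. The knockdown level was therefore 1.49%, 9.89%, 3.48% and 20.0% of scramble in these lines, and 3.62%, 12.6%, 9.31% and 36.9% of mock. Averaged over the lines, TRIM25 fell by 4.08 on the log2 scale against scramble (SE 0.077, adjusted p = 1.62e-54) and by 3.11 against mock.

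A further 8 targets with reads in each of their lines also fell against scramble, mock and the other knockdowns. Against scramble the log2 change was −4.58 (SE 0.075) for the ribosomal protein gene RPL7, −4.27 (SE 0.082) for the RNA-binding protein gene YBX1, −3.15 (SE 0.112) for the corepressor gene CTBP1, −2.56 (SE 0.104) for ZNF581 and −2.42 (SE 0.095) for the corepressor gene CBFA2T2. It was −2.01 (SE 0.097) for ZNF142, −1.79 (SE 0.099) for ZNF589 and −1.16 (SE 0.378, adjusted p = 7.26e-03) for ZMAT4, whose change was −0.79 and no longer called without replicate 1 of scramble. RPL7 has many processed pseudogenes, so its counts are uncertain. In single lines, PRRX1 fell by 5.12 in BT549 and by 3.00 in MDAMB231, FOXQ1 fell by 3.24 in MDAMB231, BNC2 fell by 2.20 in BT549, and PAX5 fell by 2.64 in MCF7. TSHZ3 fell by 3.43 in BT549 (adjusted p = 6.22e-03), a call not made against mock (−2.41) or the other knockdowns (−1.90), and by 1.98 in MCF7. HOXA11 fell by 1.26 in BT549 (adjusted p = 4.26e-03), while its change was 0.34 in T47D (adjusted p = 0.516) and −1.53 in MCF7 (adjusted p = 0.141).

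Several targets could not be checked. HOXA11, TSHZ3 and BNC2 had 0 counts in the control libraries of MDAMB231, as did FOXQ1 in those of BT549. PRRX1 lay near the floor in the controls of T47D (0.0898 CPM) and MCF7 (0.0392 CPM), as did TSHZ3 in those of T47D (0.0313 CPM). PAX5 had no reads in mock of T47D and 0.382 CPM in scramble. Changes averaged over the lines of these targets therefore include lines with little or no target transcript. FOXD4L6, which has near-identical paralogs, was at or near 0 counts everywhere. The transcripts of CNBP, IRX6, ZNF253 and NKX6 were not analysed here. The labels give only NKX6 as a target, and the count table names NKX6-1.

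**Figure D1:**
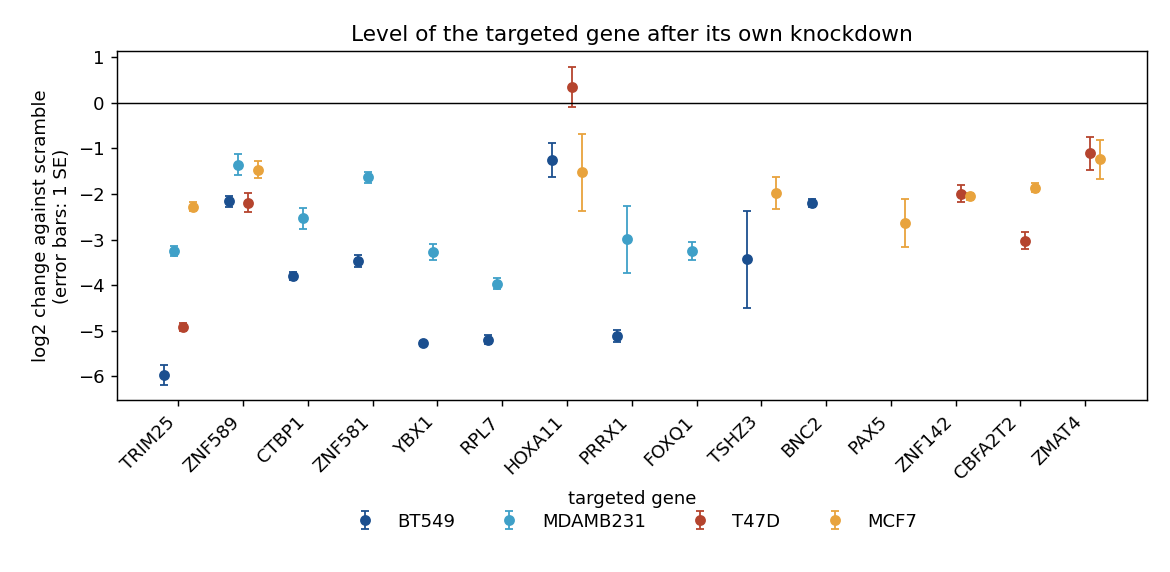
Log2 change of each targeted gene against scramble after its own knockdown, with 1 point per cell line and bars of 1 SE. TRIM25 fell in all 4 lines, by 5.96 in BT549 and by 2.28 in MCF7, and only HOXA11 in T47D lay above 0.

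The control libraries were compared with each other, since every knockdown was set against them. Interferon-stimulated genes, which cells switch on in antiviral defence, were far higher in scramble than in mock. Averaged over the 4 lines, the log2 difference was 6.75 (SE 0.323, adjusted p = 2.90e-29) for the chemokine gene CXCL10, 6.47 (SE 0.243) for the antiviral gene TRIM22, 6.35 (SE 0.293) for IFI27, 6.13 (SE 0.284) for CMPK2 and 6.01 (SE 0.299) for the antiviral gene RSAD2. In T47D, IFI27 stood at 1976 ± 17.2 CPM (SD, n = 2) in scramble and 11.8 ± 14.7 CPM in mock. The 2 mock libraries of T47D also differed in CXCL10 (0.882 ± 1.18 CPM), TRIM22 (1.14 ± 1.48 CPM) and RSAD2 (2.88 ± 3.87 CPM), and less in CMPK2 (1.12 ± 0.899 CPM). The mock baseline of these genes is therefore uncertain in T47D. The mean of the knockdowns differed from mock by −0.93, −0.66, 0.21, 0.36 and 0.07 for the 5 genes, and none of these was called. Over the whole list, 18 of 34 interferon-stimulated genes were higher in the mean of the knockdowns than in mock (19 adjusted over the list alone, median 0.39, adjusted p = 0.476 with an estimated correlation). In the same comparison 21 of 27 DNA replication genes (24 adjusted over the list alone, adjusted p = 0.0793 with an estimated correlation) and 17 of 30 mitosis genes (22 adjusted over the list alone, adjusted p = 0.465 with an estimated correlation) were lower. Of the 20 lists only MAPK and immediate early genes, with 11 of 21 higher, held (11 adjusted over the list alone, adjusted p = 0.0277 with an estimated correlation). TRIM25 itself was higher in scramble than in mock, by 1.24 in BT549, 0.29 in MDAMB231, 1.52 in T47D and 0.83 in MCF7.

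All 34 interferon-stimulated genes rose in scramble against mock (34 adjusted over the list alone, median 4.04, adjusted p = 0.016 with an estimated correlation). Of the 22 NF-kB targets, genes of inflammatory signalling, 19 rose (20 adjusted over the list alone, median 2.17, adjusted p = 0.00685 with an estimated correlation). The rise was smallest in MDAMB231, where 9 of 22 were called (median 0.59), and largest in T47D (19 of 20, median 4.42). The genes included CCL20 by 5.98, IL1B by 5.70, IL6 by 4.91 and TNF by 4.44, and the median was 1.81 with groups at 0 counts placed at their floor. All 27 DNA replication genes fell (27 adjusted over the list alone, median −0.74) and so did all 30 mitosis genes (30 adjusted over the list alone, median −1.0), each with adjusted p = 0.04 with an estimated correlation. The falls were largest in T47D, with medians of −1.89 for DNA replication and −2.04 for mitosis genes, while in BT549 14 DNA replication genes fell and 3 rose (median −0.14) and in MDAMB231 9 fell (median −0.17). KIF20A, a mitotic kinesin, fell by 1.47 and MKI67, a proliferation marker, by 1.23. Among cytosolic ribosomal protein genes 54 of 62 fell (55 adjusted over the list alone, adjusted p = 0.33 with an estimated correlation), with 58 of 62 falling in MCF7 but 5 of 61 in MDAMB231, and among ER chaperones 15 of 18 rose (15 adjusted over the list alone, adjusted p = 0.111 with an estimated correlation).

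OLFML2A, an extracellular matrix protein gene, was the only 1 of the 5 largest falls with reads in every group, at −2.31 (SE 0.128, adjusted p = 1.10e-26). With groups at 0 counts placed at the floor, the cadherin-related PCDH18 was lower by at least 2.03 on the log2 scale, XYLT1 by at least 1.33, CADM2 by at least 0.78 and the axon guidance receptor ROBO2 by at least 0.57. ESR1 was lower in scramble than in mock in T47D (101.1 ± 4.15 against 252 ± 7.46 CPM, adjusted p = 9.45e-10) and in MCF7 (129 ± 7.70 against 241 ± 2.15 CPM, adjusted p = 2.12e-10). In all, 4035 genes were higher and 3929 lower in scramble than in mock among 15390 tested, whereas 1810 were higher and 1945 lower in the mean of the knockdowns than in mock.

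**Figure D2:**
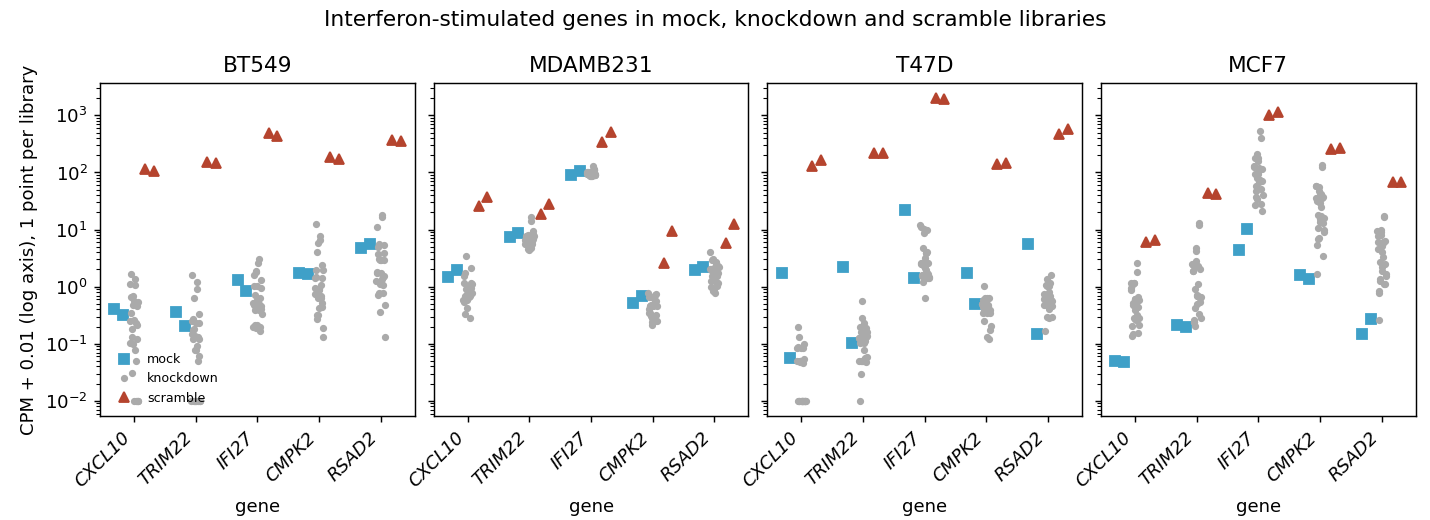
CPM plus 0.01, on a log axis, of 5 interferon-stimulated genes in each mock, knockdown and scramble library of the 4 lines, with 1 point per library. The scramble libraries lie above every other library for these genes in each line, and averaged over the lines CXCL10 was 6.75 log2 higher in scramble than in mock.

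Each knockdown was then compared with scramble in its own line, the comparison set in advance, which asks which genes depend on the target. Between 6601 and 8700 genes were called per knockdown. Against mock the range was 490 to 6158 and against the mean of the other knockdowns 425 to 7167. ZNF142 gave 8329 calls against scramble, 490 against mock and 425 against the other knockdowns, the last falling to 109 without its replicate 2 and to 105 without T47D. CTBP1 gave 7020, 5996 and 7083, and RPL7 gave 7751, 6158 and 7167. Without BT549 the CTBP1 counts were 3506 against scramble and 4160 against the other knockdowns, and the RPL7 count against scramble was 4891. Because the scramble libraries lay apart from all others, values against the mean of the other knockdowns are also given below. For targets other than TRIM25 each change is against the other knockdowns unless scramble or mock is named.

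**Figure D3:**
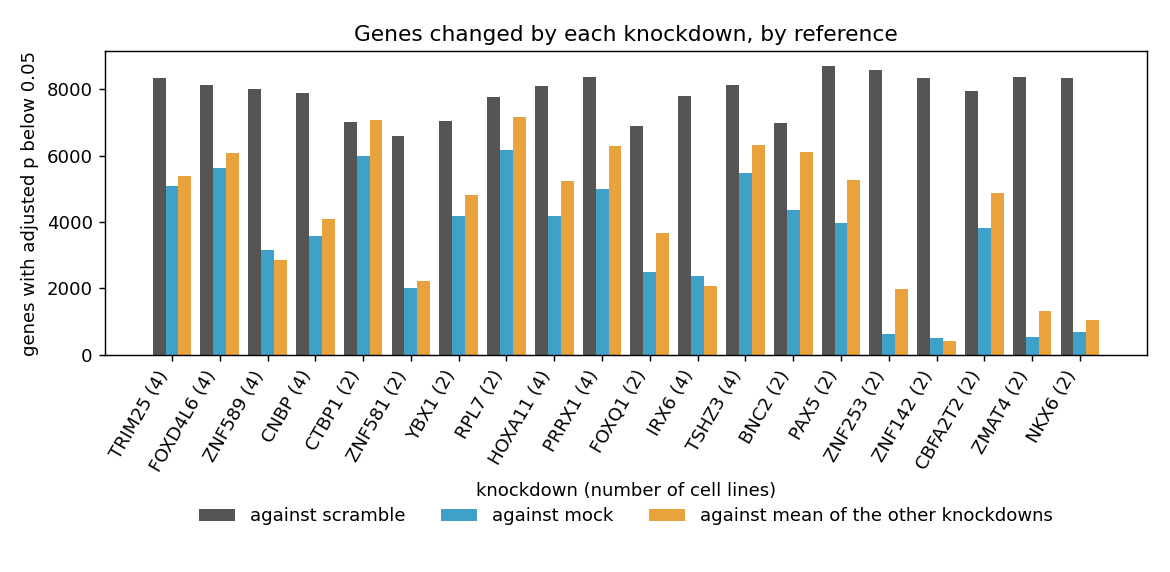
Number of genes with an adjusted p under 0.05 for each of 20 knockdowns, averaged over its 2 or 4 cell lines, against scramble, mock and the mean of the other knockdowns. Against scramble every bar lies between 6601 and 8700 genes, and against the other knockdowns between 425 and 7167.

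TRIM25 knockdown lowered interferon-stimulated genes relative to scramble in all 4 lines. TRIM22 changed by −7.08 (SE 0.263), CXCL10 by −7.04 (SE 0.327), the chemokine gene CCL5 by −6.80 (SE 0.288) and IFI44L by −6.55 (SE 0.304). The complement factor gene CFB changed by −5.76 (SE 0.235), IFI27 by −5.66 (SE 0.293), RSAD2 by −5.55 (SE 0.286) and CMPK2 by −5.24 (SE 0.28). The serum amyloid genes SAA2 and SAA1, close paralogs whose counts are uncertain, were lower by at least 4.25 and 4.58. None of these 10 genes was called against mock or against the other knockdowns, and each of them was higher in scramble than in mock.

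The largest rises against scramble were in NRCAM, a neuronal adhesion molecule gene, at 2.45 (SE 0.248), OLFML2A at 2.23 (SE 0.13), FREM2 at 2.16 (SE 0.142), NT5DC2 at 2.02 (SE 0.059, adjusted p = 2.58e-42) and IGFBP5, an insulin-like growth factor binding protein gene, at 1.84 (SE 0.422). PCDH18 was higher by at least 1.77, XYLT1 by at least 1.44, PCDHGB1 by at least 1.01, CACNA2D1 by at least 1.00 and RASGRF2 by at least 0.96. NT5DC2 alone among these 10 had at least 4 CPM in every line. Against mock only NRCAM (1.02), FREM2 (0.40) and NT5DC2 (0.37) of these 10 were called. Against the other knockdowns all but CACNA2D1 and RASGRF2 were called. OLFML2A, PCDH18 and XYLT1 were among the 5 largest falls of scramble against mock. In all, 4200 genes rose and 4123 fell against scramble.

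Relative to the mean of the other knockdowns, TRIM25 knockdown lowered SPIN4, a spindlin family gene, by 1.75 (SE 0.049, adjusted p = 8.81e-44), in each line between 1.01 and 2.39. CPOX, an enzyme gene of haem synthesis, fell by 1.69 (SE 0.058), the F-box gene FBXL17 by 1.42 (SE 0.048), the mRNA decapping enzyme gene DCP2 by 1.38 (SE 0.037) and the cap methyltransferase subunit gene RAMAC by 1.36 (SE 0.041). ATP6V1A of the vacuolar proton pump fell by 1.35 (SE 0.027), LSM6 by 1.30, CSGALNACT2 by 1.29, the prelamin A protease gene ZMPSTE24 by 1.27 and the dynein subunit gene DYNC1LI2 by 1.27. All 10 of these falls were also called against scramble and against mock. The largest rises were smaller, with GPR137B, a lysosomal membrane protein gene, at 0.78 (SE 0.037), the sialic acid exporter gene SLC17A5 at 0.60, the kinase gene RPS6KA5 at 0.60, the ERK phosphatase gene DUSP5 at 0.58, the proteoglycan gene SDC2 at 0.53 and fibronectin (FN1) at 0.52. FN1 was not called against mock and was lower against scramble (−0.23). In all, 3285 genes rose and 2095 fell against the other knockdowns, 3258 in total without replicate 2 of TRIM25.

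Among the gene lists, TRIM25 knockdown lowered 34 of 34 interferon-stimulated genes against scramble (34 adjusted over the list alone, median −3.43, adjusted p = 0.0483 with an estimated correlation) and 19 of 22 NF-kB targets (19 adjusted over the list alone, adjusted p = 0.0315 with an estimated correlation). The interferon-stimulated genes moved the other way against the other knockdowns, where 12 of 34 rose and 1 fell (12 adjusted over the list alone, median 0.29, adjusted p = 0.994 with an estimated correlation), a call not made with RLE scaling. Against mock 21 of them rose and 1 fell (25 adjusted over the list alone, median 0.65, adjusted p = 0.726 with an estimated correlation). Against scramble all 30 mitosis genes rose (30 adjusted over the list alone, adjusted p = 0.195 with an estimated correlation), as did 57 of 62 ribosomal protein genes (58 adjusted over the list alone, adjusted p = 0.29 with an estimated correlation). Against the other knockdowns, 19 of the 30 mitosis genes fell (20 adjusted over the list alone), including the kinesin gene CENPE by 0.37 and CDK1 by 0.35, with adjusted p = 0.889 with an estimated correlation. Of 25 mesenchymal and matrix genes, not called as a list against scramble, 12 rose (13 adjusted over the list alone, adjusted p = 0.0101, and adjusted p = 0.801 with an estimated correlation). FAP rose by 1.72, the gelatinase gene MMP2 by 1.17 (SE 0.21) and the collagen gene COL1A2 by 1.13, and 8 members of this list had a group at 0 counts.

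Within single lines TRIM25 knockdown changed 8791 genes in BT549, 3863 in MDAMB231, 8467 in T47D and 5809 in MCF7 against scramble. In BT549, LRRC32, a TGF-beta docking receptor gene, rose from 1.35 ± 0.177 to 29.4 ± 1.01 CPM (SD, n = 2), PLCD4 rose by 4.41 and the neuronal gene SLITRK6 by 4.2, while TRIM22 changed by −10.79, IFI27 by −10.22 and CXCL10 by −9.19. LRRC32, PLCD4 and SLITRK6 were also called against mock and against the other knockdowns (2.03, 0.62 and 2.77 on the latter reference). In MDAMB231 the water channel gene AQP3 rose by 2.95, SERPINA3 by 2.41 and NRAS by 2.29, and the antiviral genes OAS1 and IFI6 changed by −4.51 and −3.55. The cytokine gene IL24 changed by −3.52 (SE 0.384) there and was also called against mock (−1.21, adjusted p = 3.71e-02) and the other knockdowns (−1.56, adjusted p = 1.21e-03). NRAS was also called there against mock (0.35) and the other knockdowns (0.18). The MDAMB231 count was 2310 without replicate 2 of TRIM25.

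In T47D the ketogenic enzyme gene HMGCS2 rose by 4.73 against scramble and by 1.48 against the other knockdowns, FREM2 by 4.26 against scramble and the arginase gene ARG2 by 4.2. HMGCS2 was not called there against mock (0.49). Both T47D libraries of TRIM25 lay on the same side of the first principal component, so the 1.48 may also hold a difference between the sides. CCL5 stood at 0.673 ± 0.119 CPM against 3630 ± 343 CPM in scramble. The elastase inhibitor gene PI3 and the interferon gene IFNL1 had no reads after TRIM25 knockdown in T47D and lay at −11.53 and −11.04 or lower on the log2 scale against scramble, where they stood at 84.4 and 60.7 CPM. In MCF7 NELL2 rose by 2.65, NKAIN1 by 2.52 and EYA2 by 2.12, and the invariant chain gene CD74, IGFBP6 and the interferon gene IFNL2, which has close paralogs, changed by −6.47, −6.00 and −5.43. CD74 and IFNL2 were higher after TRIM25 knockdown than in mock (3.89 and 4.90). NKAIN1 was also called in MCF7 against mock (0.38) and the other knockdowns (0.56). Over the 14 knockdowns of each line, 8100 to 9272 genes were called against scramble in BT549, 2592 to 4815 in MDAMB231, 8023 to 8467 in T47D and 3762 to 6609 in MCF7.

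Whether the TRIM25 response differed between the pairs of lines was tested as the change in T47D and MCF7 minus that in BT549 and MDAMB231. The immune genes CHI3L2 (−7.38, SE 0.585), HLA-DPA1 (−6.43), HLA-DRA (−6.28) and the fatty acid enzyme gene ACSL5 (−6.03) fell more in T47D and MCF7, and SAA1 did so by at least 5.07. NKAIN1 (4.06, SE 0.467) and ATP8A2 (3.82, SE 0.428) changed in the other direction, as did CLDN9, KIAA0040 and TMEM98 by at least 2.11, 1.96 and 1.71. For CLDN9 and KIAA0040 the difference rested largely on BT549, where neither had reads after knockdown. In MDAMB231, T47D and MCF7 the changes were −0.38, −0.65 and −0.15 for KIAA0040. For CLDN9 they were −0.29, 1.75 and −0.02, so MDAMB231 and MCF7 barely differed. For TMEM98 the fitted difference was 5.36 (SE 2.231, adjusted p = 4.98e-02), with no reads after knockdown in BT549 and MDAMB231. In all, 3244 differences were positive and 2815 negative. Against mock the test called 568 and 586 genes and against the other knockdowns 785 and 963, and only the claudin gene CLDN9 of these 10 was called in all of them. HLA genes are close paralogs and their counts are uncertain.

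CTBP1 encodes a corepressor with known targets among epithelial genes. Its knockdown raised 16 of 20 epithelial genes relative to the other knockdowns in BT549 and MDAMB231 (16 adjusted over the list alone, median 1.17, adjusted p = 0.0209 with an estimated correlation). Against mock 13 rose (15 adjusted over the list alone, adjusted p = 0.0473 with an estimated correlation), and against scramble 12 rose and 1 fell (12 adjusted over the list alone, median 0.70 with groups at 0 counts at their floor, adjusted p = 0.0662 with an estimated correlation). Relative to the other knockdowns the zinc finger gene OVOL2 rose by 2.69 (SE 0.29), the protease inhibitor gene SPINT1 by 2.21 (SE 0.12), the splicing factor gene ESRP2 by 2.02 (SE 0.12) and the keratin gene KRT19 by 1.86 (SE 0.12). OVOL2 stood at low levels, 0.532 against 0.0625 CPM in BT549 and 0.37 against 0.1 CPM in MDAMB231. Rises were larger in BT549 than in MDAMB231 for SPINT1 (3.89 and 0.51), ESRP2 (2.64 and 1.37) and KRT19 (3.3 and 0.39). In BT549 14 of 15 members with enough reads rose (median 2.08) and in MDAMB231 13 of 17 (median 0.54). KRT18 stood at 192 ± 2.51 CPM (SD, n = 2) against 47.2 ± 16.5 CPM in the other knockdown libraries of BT549, and at 833 ± 123 against 535 ± 88.7 CPM in MDAMB231. E-cadherin (CDH1) rose by 0.92 (SE 0.089).

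Among single genes, CTBP1 knockdown raised FAXDC2 by 2.65 (SE 0.109), SDR16C5 by 2.65 (SE 0.178), MISP by 2.52 (SE 0.06) and the tight junction gene LSR by 2.35 (SE 0.07) relative to the other knockdowns. It lowered KBTBD6 by 3.05 (SE 0.098), the palmitoyltransferase subunit gene GOLGA7 by 2.39 (SE 0.053), the ceramide kinase gene CERK by 2.28 (SE 0.083) and the chromatin remodeller gene CHD3 by 2.06 (SE 0.073). These 8 genes were called in the same direction against scramble and mock. Of 21 ATF4 targets, genes of the amino acid response, 17 rose (17 adjusted over the list alone, adjusted p = 0.899 with an estimated correlation), a list not called against scramble. Of 30 mitosis genes 24 fell against the other knockdowns (24 adjusted over the list alone, adjusted p = 0.813 with an estimated correlation), whereas 15 rose against scramble (15 adjusted over the list alone, adjusted p = 0.777 with an estimated correlation).

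**Figure D4:**
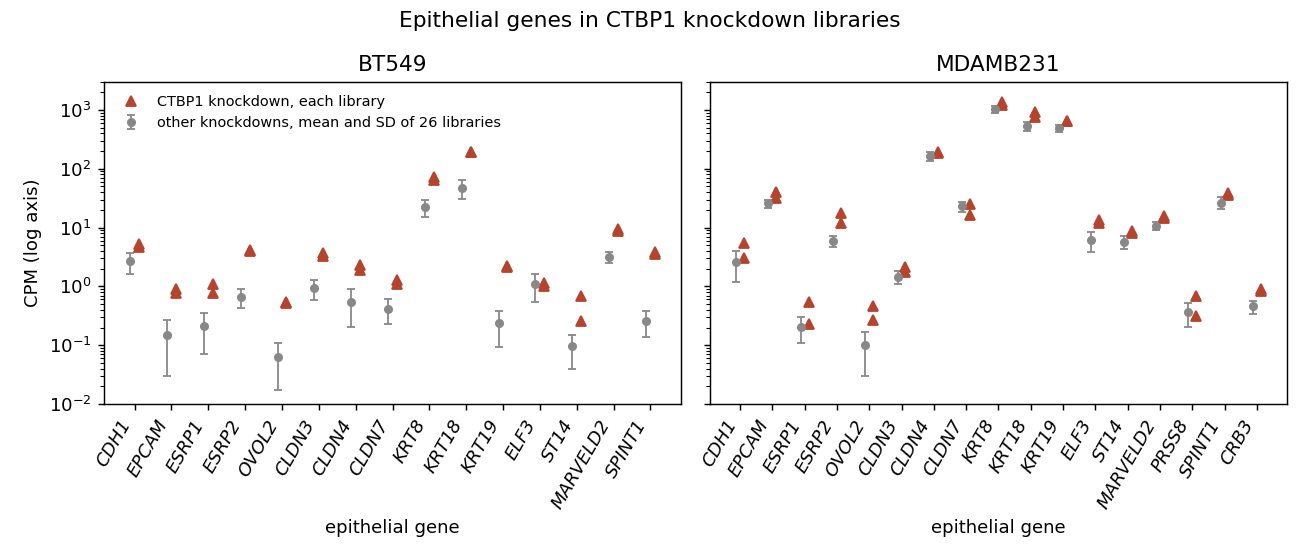
CPM on a log axis of epithelial genes in the 2 CTBP1 knockdown libraries of BT549 and MDAMB231, beside the mean and SD of the 26 libraries of the other knockdowns. In BT549, KRT18 stood at 192 CPM after CTBP1 knockdown and 47.2 CPM in the others.

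Relative to the other knockdowns, cholesterol synthesis genes moved in opposite directions after knockdown of FOXQ1 and CNBP. On that reference FOXQ1 knockdown raised 17 of 22 (17 adjusted over the list alone, median 0.26, adjusted p = 0.0209 with an estimated correlation), including the LDL receptor regulator gene PCSK9 by 0.71 (SE 0.082), HMGCS1 by 0.53 (SE 0.04), INSIG1 by 0.45 and MSMO1 by 0.42. Against scramble 17 of 22 rose and 1 fell (18 adjusted over the list alone, adjusted p = 0.116 with an estimated correlation) and against mock 9 of 22 (9 adjusted over the list alone, adjusted p = 0.284 with an estimated correlation). Relative to the other knockdowns, 16 of 22 rose in BT549 (median 0.30), where FOXQ1 had no reads in the controls. In MDAMB231, where FOXQ1 was lowered, 10 of 22 rose (median 0.24). HMGCS1 stood in BT549 at 265 CPM against 188 CPM in the other knockdowns but 271 CPM in mock. Members of the list lay on both sides of mock there, with FDFT1 at 669 against 736 CPM and MSMO1 at 174 against 152 CPM. In MDAMB231 HMGCS1 stood at 165 CPM against 91.5 CPM in mock. Relative to the other knockdowns CNBP knockdown lowered 18 of 22 (18 adjusted over the list alone, median −0.18, adjusted p = 0.0209 with an estimated correlation), including HMGCS1 by −0.39 (SE 0.031), STARD4 by −0.34, DHCR24 by −0.28 and FDFT1 by −0.27. By line, 14 of 22 fell in BT549 (median −0.18) and 14 of 22 in MDAMB231 (median −0.30). In T47D 6 of 21 fell (median −0.20), and in MCF7 5 of 21 fell and 1 rose (median −0.12). Against scramble the list was not called for CNBP (median −0.03), and against mock 16 of 22 fell (16 adjusted over the list alone, adjusted p = 0.0595 with an estimated correlation). After FOXQ1 knockdown ZSWIM7 fell by 2.68 (SE 0.073), the chaperonin gene CCT8 by 2.48 (SE 0.053) and MYBBP1A by 2.30 (SE 0.066), while CEMIP2 rose by 0.81 (SE 0.043). After CNBP knockdown FNDC3A fell by 1.37 (SE 0.036), the galactosyltransferase gene B4GALT5 by 1.33 (SE 0.048) and AIDA by 1.2 (SE 0.036), and the zinc transporter gene SLC39A10 rose by 0.74 (SE 0.032). Without 1 library per line, the FOXQ1 count of 3675 changed genes was 1833 to 2416 (1052 without BT549) and the CNBP count of 4074 was 2304 to 2631.

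Against the other knockdowns, RPL7 knockdown lowered 17 of 18 ER chaperone genes (17 adjusted over the list alone, median −0.51, adjusted p = 0.0763 with an estimated correlation), with DNAJB11 at −0.94 (SE 0.038), SDF2L1 at −0.88, CRELD2 at −0.82 and MANF at −0.81. It lowered 15 of 21 ATF4 targets (15 adjusted over the list alone, adjusted p = 0.906 with an estimated correlation), with the serine synthesis gene PHGDH at −1.72 and the asparagine synthetase gene ASNS at −1.64. Histone genes, not called against scramble, rose in 12 of 18 cases (13 adjusted over the list alone, adjusted p = 0.577 with an estimated correlation), oxidative phosphorylation genes in 27 of 32 (27 adjusted over the list alone, adjusted p = 0.813 with an estimated correlation) and ribosomal protein genes in 45 of 62 (47 adjusted over the list alone, adjusted p = 0.931 with an estimated correlation). S100A11 fell by 2.09 (SE 0.045), the copper transporter gene SLC31A1 by 2.07 (SE 0.052), PEG10 by 1.96 (SE 0.104) and the lipoprotein receptor gene SCARB1 by 1.81 (SE 0.061). The stress phosphatase subunit gene PPP1R15A rose by 1.09 (SE 0.063), which was not called against scramble (0.20), and KRT10-AS1, an antisense gene that may share reads with its partner, by 1.31.

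Against the same reference, YBX1 knockdown lowered TYW3 by 1.77 (SE 0.041), PUDP by 1.75 (SE 0.059), the microtubule severing gene KATNAL1 by 1.60 (SE 0.075) and the ribosomal protein gene RPL14 by 1.57 (SE 0.048), and raised the nucleoside transporter gene SLC29A4 by 0.94 (SE 0.103). Of 62 ribosomal protein genes 27 fell against the other knockdowns (32 adjusted over the list alone, adjusted p = 0.889 with an estimated correlation), whereas 23 rose against scramble (23 adjusted over the list alone, adjusted p = 0.792 with an estimated correlation). Without its replicate 2 the YBX1 count of 4801 genes was 2796, and without BT549 it was 1256. BNC2 knockdown lowered the actin-binding gene TAGLN by 2.00 (SE 0.122), by 3.86 in BT549, where BNC2 is transcribed, and by 0.15 in MDAMB231. Its count of 6107 genes was 818 without BT549. The guanylate-binding protein gene GBP1 fell by 1.74 (SE 0.154), MX1 by 1.67 (SE 0.256) and the immune ligand gene PDCD1LG2 by 1.52 (SE 0.131). Ribosomal protein genes fell in 58 of 62 cases after BNC2 knockdown (58 adjusted over the list alone, adjusted p = 0.578 with an estimated correlation), a list not called against scramble, and mitosis genes rose in 28 of 30 (28 adjusted over the list alone, adjusted p = 0.577 with an estimated correlation). Of 24 metastasis genes 10 fell (10 adjusted over the list alone, adjusted p = 0.788 with an estimated correlation), among them the adhesion molecule gene VCAM1 by 2.43 and ADAMTS1 by 0.83. ZNF581 knockdown lowered GXYLT1 by 1.52 (SE 0.052) and ZNF275 by 1.33 (SE 0.059). Its count of 2206 genes was 785 to 852 without 1 library per line and 432 without BT549.

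Of the targets in all 4 lines, FOXD4L6 knockdown, against the other knockdowns, lowered the ubiquitin ligase gene MARCHF2 by 2.14 (SE 0.061), the single-stranded DNA binding gene RPA1 by 1.83 (SE 0.033), the Wnt receptor gene FZD5 by 1.70 (SE 0.059) and UHMK1 by 1.59 (SE 0.04). On that reference it lowered 26 of 27 DNA replication genes (26 adjusted over the list alone, median −0.38, adjusted p = 0.147 with an estimated correlation), with RFC3 at −0.89 and MCM2 at −0.82. Against scramble 18 of the 27 rose (19 adjusted over the list alone, median 0.19, adjusted p = 0.707 with an estimated correlation). OAS2 and MX1, interferon-stimulated genes, rose by 1.08 (SE 0.141) and 0.98 (SE 0.138) but were lower against scramble (−4.16 and −3.30). HOXA11 knockdown lowered the tubulin gene TUBB2A by 2.00 (SE 0.092), the zinc transporter gene SLC39A1 by 1.78 (SE 0.032) and the peroxisomal gene CROT by 1.73 (SE 0.05), and raised 25 of 27 DNA replication genes (25 adjusted over the list alone, adjusted p = 0.312 with an estimated correlation), among them RRM2 by 0.65. PRRX1 knockdown lowered MRPL24 by 2.06 (SE 0.058), the phosphatase gene PTPN1 by 1.84 (SE 0.043) and the protease gene CTSB by 1.80 (SE 0.055). Hypoxia and glycolysis genes fell in 16 of 21 cases after PRRX1 knockdown (16 adjusted over the list alone, adjusted p = 0.669 with an estimated correlation), a list not called against scramble, with ANKRD37 at −0.77 and HK2 at −0.71.

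Against the other knockdowns, TSHZ3 knockdown lowered RTL8B by 2.19 (SE 0.045) and RTL8C by 1.70 (SE 0.039), which are paralogs, and the ubiquitin ligase gene STUB1 by 1.88 (SE 0.049). ER chaperone genes rose in 15 of 18 cases after TSHZ3 knockdown (16 adjusted over the list alone, adjusted p = 0.312 with an estimated correlation), including DNAJB9 by 0.62, while against scramble the list was not called (median −0.09). ZNF589 knockdown lowered the ornithine aminotransferase gene OAT by 1.58 (SE 0.037) and GSKIP by 1.44 (SE 0.043), and raised SLC33A2 by 0.48 (SE 0.057). IRX6 knockdown lowered FBXO9 by 0.64 (SE 0.028) and the phosphatase gene PTPN11 by 0.50 (SE 0.029), and raised ZNF778 by 0.54 (SE 0.041). The rule also named DANCR (−0.44) and ZCCHC2 (0.37) for IRX6, which went the opposite way against scramble (1.09 and −0.84). Without 1 library per line, the ZNF589 count of 2852 genes was 1250 to 1454 and the IRX6 count of 2055 was 903 to 1062 (977 without BT549).

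In T47D and MCF7, CBFA2T2 knockdown raised 33 of 34 interferon-stimulated genes relative to the other knockdowns (34 adjusted over the list alone, median 0.87, adjusted p = 0.455 with an estimated correlation). Both T47D libraries of CBFA2T2 lay on the same side of the first principal component, and the list was not retested with that side as a term. OAS1 rose by 1.56 (SE 0.171), OAS2 by 1.48 (SE 0.189) and IFI27 by 1.43 (SE 0.239). These 3 were also higher than in mock and, like the whole list, lower than in scramble, while GPAT3 fell by 1.49 (SE 0.107) and the annexin gene ANXA7 by 1.31 (SE 0.032). PAX5 knockdown lowered 31 of 34 interferon-stimulated genes (31 adjusted over the list alone, median −0.88, adjusted p = 0.60 with an estimated correlation), with OAS2 at −1.93 (SE 0.271) and IFIT3 at −1.68 (SE 0.329), neither of them called against mock. It raised 15 of 22 p53 targets, not called against scramble (15 adjusted over the list alone, median 0.38, adjusted p = 0.115 with an estimated correlation), with EDA2R at 1.19, TP53INP1 at 1.18 (SE 0.072), ZMAT3 at 0.88 and the death receptor gene FAS at 0.67, and lowered the replication gene WDHD1 by 1.95 (SE 0.076). Without 1 library per line the CBFA2T2 count of 4860 genes was 2907 to 2924 (2321 without T47D), and without replicate 2 the PAX5 count of 5271 was 3493.

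Relative to the other knockdowns, ZNF253 knockdown raised 30 of 30 mitosis genes (30 adjusted over the list alone, median 0.35, adjusted p = 0.134 with an estimated correlation), with KIF20A at 0.47 and NUSAP1 at 0.46, and lowered the glycosyltransferase gene GALNT7 by 1.26 (SE 0.07), PDCD4 by 0.96 (SE 0.05) and the DNA repair gene TDG by 0.91 (SE 0.055). ZNF142 knockdown lowered the kinase gene NEK3 by 1.39 (SE 0.101) and ALKBH1 by 0.76 (SE 0.054). ZMAT4 knockdown lowered RAB8B by 0.74 (SE 0.058) and IKBKG, a regulator of NF-kB signalling, by 0.71 (SE 0.082). NKX6 knockdown lowered DNASE1L1 by 1.32 (SE 0.056), the integrin gene ITGA5 by 0.97 (SE 0.073) and FERMT2 by 0.86 (SE 0.04), and 8 of 26 oestrogen-responsive genes rose (12 adjusted over the list alone, adjusted p = 0.115 with an estimated correlation). Without 1 library per line the counts fell from 1967 to between 774 and 1242 for ZNF253, from 1330 to between 241 and 821 for ZMAT4 and from 1033 to between 268 and 409 for NKX6. With the T47D side of the first principal component as a term, the ZNF142 count rose from 425 to 750.

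For these 19 targets the rule set in advance, applied against scramble, named mainly interferon-stimulated and inflammatory genes among the falls. The 76 places were taken by 17 genes, with TRIM22 named for 16 targets (−9.82 to −5.33), CXCL10 for 14, CCL5 for 12 and IFI44L for 9, and each of the 17 was higher in scramble than in mock. The 76 rises were spread over 42 genes, led by ROBO2 for 8 targets, RAB3B for 5 and LINC01963 and OLFML2A for 4 each, and 74 of the 76 were below 4 CPM in a line tested.

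Over all 400 pairs of a list and a target, 192 were called against scramble, 84 higher and 108 lower, and 30 of them held with an estimated correlation. Interferon-stimulated genes and NF-kB targets were lower for all 20 targets, and these calls held with an estimated correlation for 9 and 17 of them. Mitosis genes were higher for all 20 targets, ribosomal protein and oxidative phosphorylation genes for 19 each and DNA replication genes for 14 (lower for 1), while ER chaperones and metastasis genes were lower for 18 each and MAPK and immediate early genes for 10. Of these calls only those of DNA replication genes for 3 targets and of ER chaperones for 1 target held with an estimated correlation. Nucleolar ribosome assembly genes and YAP and TGF-beta targets were lower for 6 targets each, histone genes and ATF4 targets for 3 each, oestrogen-responsive genes were higher for 5, cholesterol synthesis genes for 4 (lower for 1), and hypoxia and glycolysis genes for 2. Epithelial genes were higher for 1 target and lower for 2, and none of the calls of these 8 lists held with an estimated correlation. The p53 targets, the mesenchymal and matrix genes and the stromal and immune cell markers were called for no target against scramble. Against the other knockdowns 139 pairs were called, 63 higher and 76 lower, of which the 3 described for CTBP1, FOXQ1 and CNBP held with an estimated correlation, and stromal and immune cell markers were again called for no target. Against scramble, 69 of the 139 were called in the same direction, 33 in the opposite direction and 37 not at all. The rule for named genes, repeated on the other knockdowns, filled 172 places over all 20 targets, not all of them given above. Of these, 150 were called in the same direction against scramble, 18 in the opposite direction and 4 not at all.

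**Figure D5:**
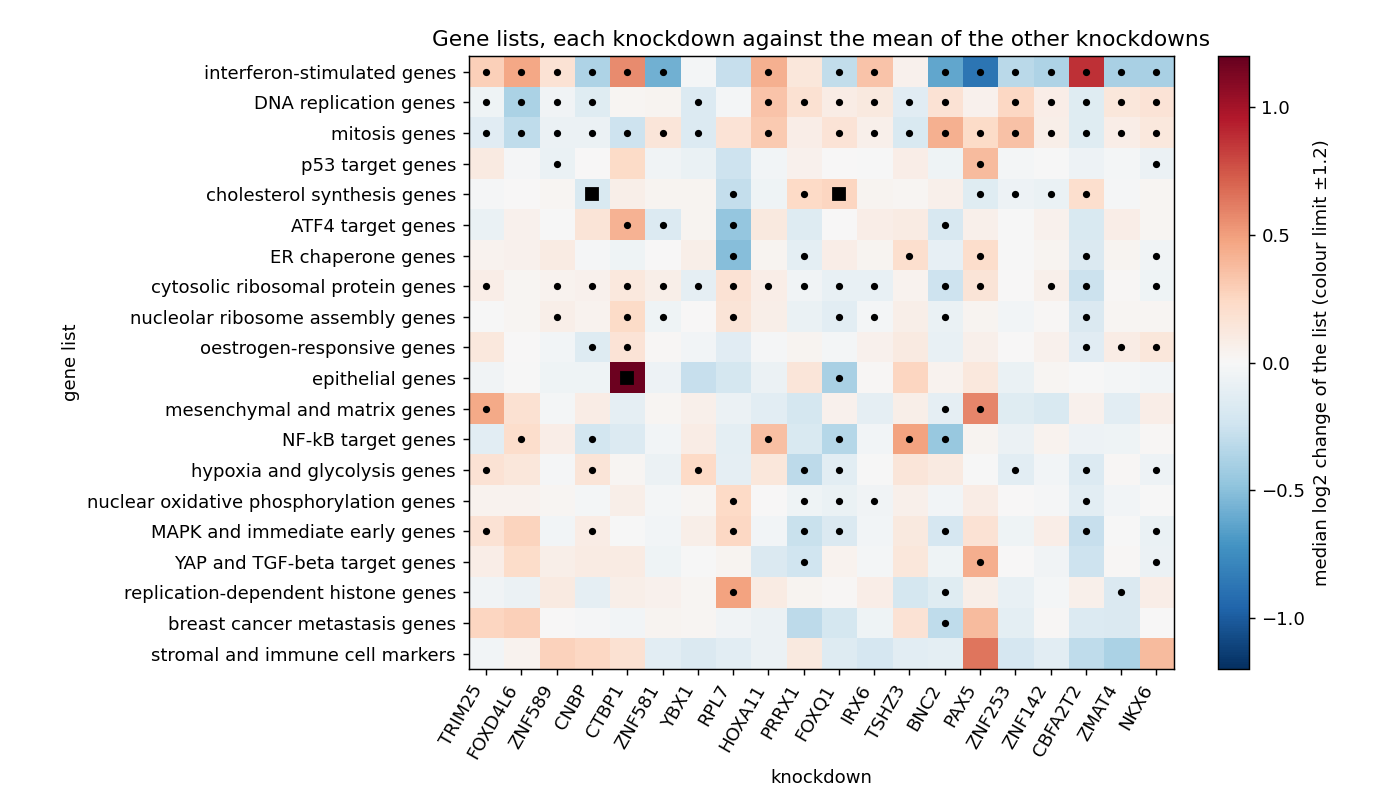
Median log2 change of 20 gene lists for each of 20 knockdowns against the mean of the other knockdowns, with dots for lists called by camera and squares for those also called with an estimated correlation. The 3 squares are the epithelial genes after CTBP1 knockdown and the cholesterol synthesis genes after knockdown of CNBP and FOXQ1.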

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

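The tests of library depth, of the cell line of origin and of transfected RNA for the scramble libraries, of foreign RNA and of grouping for T47D, and of the targeted transcript, were chosen only after the result was seen.

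The TRIM25 response against scramble differed between T47D and MCF7 on the 1 side and BT549 and MDAMB231 on the other for 15 named genes. Of the 20 genes named for the averaged change 6 differed, and the other 9 were named because they were among the largest differences, so their test restates that choice. The fitted log2 differences were 0.92 for NT5DC2, −1.98 for PCDHGB1, −3.21 for CCL5, −4.46 for CFB, −1.73 for RSAD2, −6.85 for SAA1, 5.36 for TMEM98, 4.06 for NKAIN1, 3.88 for CLDN9, 3.82 for ATP8A2, 3.73 for KIAA0040, −7.38 for CHI3L2, −6.43 for HLA-DPA1, −6.28 for HLA-DRA and −6.03 for ACSL5. Groups without reads leave only bounds for SAA1, TMEM98, CLDN9, KIAA0040 and PCDHGB1, whose differences were at least 5.07, 1.71, 2.11, 1.96 and 0.08 in size. A single control library lay far above the other 3 of its line for 4 targeted genes, namely PRRX1 in a mock library of T47D (0.28 CPM), PRRX1 in a scramble library of MCF7 (0.157 CPM), TSHZ3 in a scramble library of T47D (0.125 CPM) and PAX5 in a scramble library of MCF7 (1.09 CPM). Of 68 such groups tested, chance alone gives a single library far from the others in about 1 in 20.

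The scramble libraries lay apart from mock and knockdown libraries in every line. Their median total count was 0.971 times that of the other libraries, which argues against depth, and 8 of 8 scramble libraries correlated best with the mock libraries of their own line, which argues against RNA of another line. For the interferon-stimulated genes the median change of the knockdown mean against mock was 0.0957 times that of scramble against mock, which argues against transfected RNA of any kind as the whole source. The mock libraries of T47D differed between them in several genes of that list, which makes the ratio less certain. Against mock that list was higher for 12 of the 20 knockdowns and lower for 5 (highest median 1.78), none with an estimated correlation, so a smaller effect of transfected RNA stays open. A response to the sequence or preparation of the scramble RNA was not tested, and the design gives no second scramble, so it stays open.

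The T47D libraries other than scramble lay on 2 sides of their first principal component. The ratio of median total counts between the sides was 1.06, and the estimated percent of RNA from another line differed by at most 0.0964 percentage points, which argues against depth and against RNA of other lines. In 11 of 15 groups the 2 libraries lay on opposite sides, which argues against the knockdown as the source. TRIM25, FOXD4L6, ZNF589 and CBFA2T2 had both T47D libraries on the first side, while mock and the remaining knockdowns had them split. For these targets, T47D changes against mock or the other knockdowns therefore also hold a difference between the sides. Counts and named genes were refitted with the side as a term on these references, but gene lists were not. A difference in culture or handling between the sides stays open, since the labels give no batch, and no biological explanation was tested.

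Knockdowns changed genes in lines where the targeted gene was not detected. In 4 such cases, HOXA11, TSHZ3 and BNC2 in MDAMB231 and FOXQ1 in BT549, the count exceeded that of every pair of libraries drawn from different knockdowns of the line. This argues against error that differs between the 2 libraries of a group as the whole source. Error shared by both libraries of a group, such as from a shared culture, is not excluded, because no drawn pair came from the same group. Loss of the targeted transcript would put such counts below those of every knockdown with a detected and lowered target in that line, which held in 0 of the 4 cases. In 2 of the 4 the count exceeded the median of those knockdowns, and in 2 it did not, so other effects of the knockdown are not told apart from loss of a transcript below the floor. FOXD4L6, at or near 0 counts in every line, was set aside from these cases because its near-identical paralogs make its counts uncertain. Against the other knockdowns it gave 6650 calls in BT549 and 1768 in MDAMB231, where those medians were 6971 and 1320. It gave 1936 calls in T47D and 4624 in MCF7. The split of 2 and 2 rests on the cutoff of 3 counts, which leaves out targets near the floor. Against the other knockdowns, PRRX1 gave 2510 calls in T47D and 3610 in MCF7. In T47D, PAX5 gave 2718 and TSHZ3 2310. The medians over all knockdowns were 1074 in T47D and 2480 in MCF7. These targets were not set beside drawn pairs. Effects on other transcripts were not tested.

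Other splits of the libraries were counted, with fewer than 100 drawn because of limited time, in a model of the line and the treatment on only the libraries split, so its counts are smaller than the reported ones. Against scramble, only the real split gave as many genes for TRIM25 (6135, highest other 2.2% of that, 1 of 40 splits), for the other 7 targets of all 4 lines (4673 to 6219, highest other 59, 1 of 25 splits each) and for scramble against mock (5928, highest other 704, 1 of 25 splits). Since mock alone differed from scramble by 5928 genes, splits against scramble cannot tell an effect of a target from the shift of the scramble libraries. The difference between the pairs of lines gave 2623 genes in the real split and 2618 in another (1 of 25 splits as large), where the fit over all libraries called 6059. That other split kept TRIM25 and scramble apart in BT549 and MDAMB231 and swapped them in T47D, so it still holds a knockdown difference between lines. For the 12 targets of 2 lines only 18 splits exist against scramble, with 1 of 18 as large (2160 to 6190, highest other 375), too few to reach 0.05. Against the other knockdowns, the real count was set beside 24 draws of 2 libraries per line from all knockdown libraries, shared by all targets of the same lines. On that count 1 of 25 splits was as large for the 8 targets of all 4 lines (95 to 3449, highest other 74), for BNC2 (1606), CTBP1 (3361), RPL7 (3550) and YBX1 (644), with 577 as the highest other, and for CBFA2T2 (2168) and PAX5 (2309), with 197. It was 2 of 25 splits for FOXQ1 (174) and ZNF581 (69), with 577 as the highest other, 4 of 25 splits for ZNF253 (105) and 5 of 25 splits for ZNF142 (25), ZMAT4 (21) and NKX6 (36), with 197, so for these 6 chance is not excluded in this smaller model. The model held no term for the T47D side, although a draw could take both T47D libraries from the same side. Nor can these draws exclude error shared by the 2 libraries of a group.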

How the results depend on the processing

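The T47D side term, the term for library order, and every value against the other knockdowns reported as a result of its own, were chosen only after the result was seen. RLE size factors, no low-count filter and DESeq2 left all 56, 46 and 55 main results they could give within 1.5 times and on the same side of the threshold, and among single named genes RLE and DESeq2 each ended 1 call. Other settings ended far more calls of named genes. Leaving out 1 line ended 90 and kept 902 over all such fits. Of the calls against scramble, mock as the control ended 115, turned the sign of 46 and kept 45. The mean of the other knockdowns ended 94, turned 47 and kept 65. Both controls together ended 34 and kept 172. No paired analysis was possible because the labels number the libraries of the series in a row and give no replicate number shared between groups, so the order of the 2 libraries of a group was tried as a term per line. It left all 55 main results it could give within 1.5 times and on the same side of the threshold, with the TRIM25 count within MDAMB231 at 4821, and ended no call of a named gene. The difference between the second and the first library correlated over the groups of a line with a median of 0.047 in BT549, 0.428 in MDAMB231, 0.011 in T47D and 0.099 in MCF7, above 0.1 in 40, 91, 41 and 58 of 120 pairs of groups. In T47D it ranged from −0.838 to 0.852, since of the 11 groups with libraries on both sides 9 had the first library on the second side and 2, NKX6 and mock, the reverse. Where a left-out library leaves 1 library in a group, that library is assumed to vary like the other groups. A level below 0.0484 to 0.0777 CPM in 1 library cannot be told from 0. This limits FOXD4L6, HOXA11, PRRX1, FOXQ1, TSHZ3, BNC2 and PAX5 in the lines with few or none of their reads. For every change listed below except those from fewer libraries or lines the cause was not tested.

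Gene list calls against scramble fell to 30 of 192 with an estimated correlation. With mock as the control, counts over 1.5 times smaller than against scramble were TRIM25 5088, ZNF589 3145, CNBP 3578, ZNF581 2018, YBX1 4164, HOXA11 4188, PRRX1 4995, FOXQ1 2500, IRX6 2357, BNC2 4373, PAX5 3960, ZNF253 620, ZNF142 490, CBFA2T2 3829, ZMAT4 527 and NKX6 671. Within lines the TRIM25 count was MDAMB231 1727, T47D 1323 and MCF7 3019, and the difference between the pairs of lines was called for 1154 genes. HOXA11 in T47D stood at −0.71 and TSHZ3 in BT549 at −2.41. With the mean of the other knockdowns as the reference, the counts were TRIM25 5380, ZNF589 2852, CNBP 4074, ZNF581 2206, HOXA11 5245, FOXQ1 3675, IRX6 2055, PAX5 5271, ZNF253 1967, ZNF142 425, CBFA2T2 4860, ZMAT4 1330 and NKX6 1033, within lines for TRIM25 MDAMB231 1630, T47D 1470 and MCF7 2198, and 1748 for the difference between the pairs of lines, with HOXA11 in T47D at −0.76 and TSHZ3 in BT549 at −1.90. With both controls as 1, the TRIM25 count was MDAMB231 2440 and MCF7 3515, and 3797 for the difference between the pairs.

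Leaving out 1 line, or 1 library per line, moved these counts by over 1.5 times, given from the lowest to the highest over all such fits. Against scramble they were CTBP1 3506 to 7760, ZNF581 3508 to 7341, YBX1 3742 to 7758, RPL7 4891 to 8133, FOXQ1 3425 to 7576, BNC2 3551 to 8366, PAX5 5642 to 9008, ZNF253 5264 to 8842, ZNF142 4855 to 8803, CBFA2T2 3756 to 8711, ZMAT4 4979 to 8695 and NKX6 4902 to 8797. Against the other knockdowns they were TRIM25 3258 to 5234, ZNF589 1250 to 2741, CNBP 2304 to 3751, CTBP1 4160 to 7468, ZNF581 432 to 2739, YBX1 1256 to 5120, FOXQ1 1052 to 3649, IRX6 903 to 2472, BNC2 818 to 7727, PAX5 3493 to 3888, ZNF253 774 to 1242, ZNF142 105 to 291, CBFA2T2 2321 to 4298, ZMAT4 241 to 823 and NKX6 268 to 951. Within MDAMB231 the TRIM25 count was 2310 to 3542, and the level of ZMAT4 changed by −1.43 to −0.79. With the T47D side as a term ZNF142 rose to 750.

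The sign of a named gene's change against scramble turned with mock as the control in these cases, all of them log2 values. For TRIM25 PCDH18 −0.21, OLFML2A −0.08, CFB 0.06, IFI27 0.69, RSAD2 0.46 and CMPK2 0.89, for the TRIM25 difference between the pairs of lines KIAA0040 −0.04 and HLA-DRA 1.09, for TRIM25 within MDAMB231 AQP3 −0.25, OAS1 0.60 and IFI6 0.49, for TRIM25 within T47D FREM2 −0.37, for TRIM25 within MCF7 NELL2 −0.64, CD74 3.89, IGFBP6 0.58 and IFNL2 4.90, for FOXD4L6 CXCL10 0.37 and TRIM22 0.57. For ZNF589 IFI27 0.35, for CNBP PCDH18 −0.90, for CTBP1 PTGIS −0.02 and CXCL10 0.09, for ZNF581 PTGIS −0.39, for YBX1 PCDHGB1 −0.04, for HOXA11 OLFML2A −0.27, TRIM22 0.13 and IFI44L 0.32. For PRRX1 OLFML2A −0.13 and IFI27 0.10, for FOXQ1 PTGIS −0.30, for IRX6 OLFML2A −0.36 and PCDHGB1 −0.06, for TSHZ3 OLFML2A −0.18, for PAX5 PCDH18 −0.36, for ZNF253 RAB3B −0.10, LINC01963 −0.45 and CFB 0.45. For ZNF142 RAB3B −0.36 and LINC01963 −0.19, for CBFA2T2 PCDH18 −0.79 and RAB3B −0.60, for ZMAT4 RAB3B −0.51, LINC01963 −0.05 and HLA-DRA 0.08, for NKX6 RAB3B −0.82 and CFB 0.54.

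The sign of a named gene's change against scramble turned with the mean of the other knockdowns as the reference in these cases, all of them log2 values. For TRIM25 TRIM22 0.05, CXCL10 0.69, CCL5 0.04, IFI27 0.52, RSAD2 0.42 and CMPK2 0.58, for the TRIM25 difference between the pairs of lines CHI3L2 0.91, SAA1 0.24, HLA-DPA1 0.13 and HLA-DRA 0.33, for TRIM25 within BT549 CXCL10 0.18, for TRIM25 within MDAMB231 OAS1 0.29 and IFI6 0.38, for TRIM25 within T47D FREM2 −0.30, ARG2 −0.01 and CCL5 0.40, for TRIM25 within MCF7 NELL2 −0.16, CD74 0.42 and IFNL2 0.73. For FOXD4L6 CXCL10 1.40, IFI44L 0.19, CCL5 0.53 and TRIM22 1.32, for ZNF589 CXCL10 0.85, TRIM22 0.67, CCL5 0.48 and IFI27 0.15, for CTBP1 CXCL10 1.21, IFI44L 0.58 and TRIM22 0.80, for ZNF581 CXCL10 0.48, for YBX1 CXCL10 0.62, for HOXA11 CXCL10 0.80, CCL5 0.26, TRIM22 0.85 and IFI44L 0.96. For PRRX1 TRIM22 0.51, for IRX6 CXCL10 0.25, TRIM22 0.53 and CCL5 0.82, for TSHZ3 TRIM22 0.59, IFI44L 0.07 and CCL5 0.62, for ZNF253 SAA1 0.10, for CBFA2T2 RAB3B −0.09 and CHI3L2 1.13, for NKX6 RAB3B −0.32.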

Other observations

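The comparison below was chosen only after the result was seen. In T47D, single genes differed strongly between the 2 libraries of the 11 groups that lay on both sides of the first principal component. FOXJ1, the transcription factor of motile cilia, was higher on the first side by 5.05 ± 0.36 log2 (SD over 11 groups), CFAP126 by 5.88 ± 0.62, RSPH4A by 3.97 ± 0.67 and HYDIN by 3.61 ± 0.57. Higher on the second side were CLEC3A (−5.34 ± 0.49), the aryl hydrocarbon receptor target CYP1A1 (−3.43 ± 0.36), CHAC1 (−2.24 ± 0.36), the fatty acid receptor gene CD36 (−1.98 ± 0.18) and the stress-induced cytokine gene GDF15 (−1.56 ± 0.52). Each gene had the same sign in all 11 groups, and these genes were picked because they separate the sides.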
